A study of Sus scrofa with 40 samples.

How the data were processed

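The deposited data were per-library transcript assemblies of pig liver and longissimus dorsi muscle, from paired reads of 76 bp. Per the labels' protocols, libraries were sequenced on a HiSeq2000 with several samples in a lane, and lane membership was not given in the sources used here. The labels call the early and late groups batches, so slaughter batch and time are the same thing. Per the submitters' processing notes, the authors used FastQC, Trim Galore, TopHat2 2.1.0 and Cufflinks 2.2.1 with the Sscrofa11.1 build. The deposited FPKM values are those that Cufflinks gave to each assembled transcript of a library, per the file headers and attributes. Transcript identifiers were not shared between libraries, so assembled transcripts were assigned to RefSeq genes of Sscrofa11.1 by position (27467 placed genes; 17673 had a value in at least 1 library), with at least 0.5 of their exonic bases inside the gene body. The annotation used gave gene bounds without exons or strand, so exon and intron positions are not stated, and overlapping or neighbouring genes and close copies are uncertain. The file of liver late control animal 3 held only masked regions, namely chromosome 8 from 69643389 to 69666327 (ALB) and from 74552867 to 74612588 (FGA, FGB and FGG) and the mitochondrial genome. ALB had a value in 0 of 19 livers, FGA, FGB and FGG in 9, and ACTA1, MYH1, MYH2 and MYH4 in 0 of 20 muscles. No mitochondrial transcripts were measured. No library's gene values were identical to another's. The animals are separate pigs, so the limma p-values of single genes measure the spread between animals. The p-values of gene lists at a preset correlation compare a list with the other genes. The permutation p between cell type lists shuffles genes. Neither of these measures how far a list varies between animals.

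Before the data were examined, the groups, contrasts, tests, 32 gene lists, the rule for named genes and most alternatives were fixed. A gene's FPKM was the sum over the transcripts of the gene, libraries were rescaled by a median of ratios, and genes with a mean FPKM of at least 1 in a tissue were tested on log2(FPKM + 1). limma 3.58.1 in R 4.3.3 fitted the 4 groups of a tissue together (8 groups for the tissue interaction), with eBayes and a trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Lists of at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a tissue and contrast, and again with an estimated correlation and with fry. Python 3.11.15 assigned the transcripts. Single values of groups were compared with exact permutation tests, two-sided.

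Some choices were made after the data were seen. A gene that was not assembled in a library was treated as missing, not as 0, and a gene needed a value in 3 libraries of each group. The planned gene value was compared with others after the files were seen: first the single longest assembled gene, then the mean over consensus exonic bases, which had the smallest spread and was for a time used for the results, and then a sum over transcripts of at least 300 bp. The analysis then returned to the planned sum, so the results of the others had been seen by then, and they stand as added alternatives. The median spread within groups (log2 SD) in liver and muscle was 0.391 and 0.327 for the planned sum, 0.298 and 0.231 for the longest gene, 0.258 and 0.204 for consensus bases and 0.378 and 0.319 for the sum from 300 bp. Genes called over time in liver were 471, 714, 1199 and 588 in that order, and in muscle 1264, 2091, 2563 and 1331. Genes called for the late diet in liver were 1, 0, 0 and 1, and for diet by time in liver 1, 0, 0 and 2.

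Transcripts under 300 bp held 96.9% to 99.1% of the summed FPKM of a liver library and 96.9% to 99% of a muscle library, because Cufflinks gives very short transcripts very large FPKM. They held over 50% of the FPKM in 151 of 11989 tested liver genes and 91 of 10910 muscle genes, with a median over genes of 0%. Of 126 combinations of a named gene and a tissue, 5 were so affected. Total FPKM was therefore not read as depth, and the median of ratios does not depend on those genes.

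The genes named were, for each early and late diet contrast, the 8 highest and 8 lowest changes among genes that passed (the 6 smallest p where none passed), the 3 members with the smallest p of each list that passed (or of the 3 lists with the smallest p), and genes fixed per tissue. For the time contrasts and the diet over both times they were the 6 highest and 6 lowest changes among genes that passed and 2 members of up to 6 lists, and for interactions the 4 smallest p of each sign among genes that passed. Not all genes so picked are reported, and which of them are was decided after their values were seen. The steps were tested on simulated data with 200 changed genes, 100 of each size, and noise drawn independently for each gene. The shares recovered therefore do not give the power where few genes change or where genes vary together. For the early liver diet contrast 51% of genes changed by 1 log2 unit and 93% of those changed by 2 were recovered. For late liver these were 52% and 93%, for early muscle 64% and 95%, for late muscle 63% and 95%, for the liver time contrast 77% and 98%, for muscle time 91% and 100%, and for the tissue interaction 33% and 87% early and 37% and 83% late. False calls numbered 4 to 14 over these comparisons. Alternatives covered the pseudocount, filter, scaling, variance model, library weights, threshold, replicate block and gene value, and leaving out each library.

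Liver and muscle samples that share a group and an individual number were taken to come from the same animal. The deviations of such pairs from their group means had a mean correlation of 0.000624 against −0.000202 for other pairs, and 5 of 19 animals matched their own muscle best (permutation p = 0.49, one-sided). For the sum from 300 bp the values were 0.0468 against −0.0116, and 12 of 19 (permutation p = 1e-04, the smallest that 10000 resamples can give). The animal as a block in the tissue interaction changed no call.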

Results

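Liver and longissimus dorsi muscle, a back muscle, were profiled by RNA sequencing in 20 castrated male pigs from a Duroc × Iberian cross. The pigs were fed either a control diet or an isoenergetic diet with 11% crude protein and 0.60% lysine, and were slaughtered either at day 20 of the diets (early) or when the growing period ended (late). Tissue, time and diet made 8 groups of 5 animals. The file of liver late control animal 3 held only masked regions and no transcripts, so that group had n = 4 and 39 libraries were analysed, 19 of liver and 20 of muscle. Each liver library held 36190 to 60223 assembled transcripts and each muscle library 26680 to 38625. Read totals were not given in the sources used here. The read coverage that corresponded to 1 FPKM was 4.33 to 7.88 in liver and 4.89 to 7.89 in muscle. Values below are rescaled FPKM as mean ± SD, and log2 changes are on the log2(FPKM + 1) scale with their standard error, which understates the change of genes with low values.

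The first question was what the low-protein diet did in liver at day 20. Transcripts of cytosolic ribosomal proteins, the protein part of the ribosome, were higher as a group: 62 of 76 measured members lay above control, with a median log2 change of 0.36. RPLP0 stood at 466 ± 69.3 FPKM (n = 5) against 323 ± 68.9 (n = 5) in controls, and RPL36 at 368 ± 111 against 185 ± 76.7. Chaperones, a list of heat shock proteins and of folding genes of the endoplasmic reticulum, were higher in 20 of 24 members, among them the calcium-binding chaperone CALR (326 ± 99.9 against 204 ± 29.1 FPKM, n = 5 each). Acute phase proteins, which the liver secretes in inflammation, were higher in 12 of 15 members, with a median of 0.59, and included the orosomucoid ORM1 (5950 ± 1480 against 2360 ± 1130 FPKM, n = 5 each) and the iron hormone HAMP (53.2 ± 62.7, n = 5, against 5.29 ± 4.13, n = 4). By limma's camera with a preset correlation these 3 lists rose, with adjusted p = 2.01e-12, 2.92e-05 and 0.000672. With an estimated correlation none of them passed, each at adjusted p = 0.3. When the early livers were split at random, 2, 3 and 3 of 100 splits gave a camera p as small, the real split included. Of single genes, limma called 0 of 11989 at an adjusted p under 0.05, and 788 had an unadjusted p under 0.05 where chance gives 599. Adjusted over the list alone, 4 acute phase genes passed and 0 members of the other lists named here and in the next paragraph.

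Further lists passed in early liver, but not without certain libraries. Nuclear-encoded oxidative phosphorylation rose (39 of 47 members higher, adjusted p = 0.00274), as did fatty acid and triglyceride synthesis (15 of 21, adjusted p = 0.0113), macrophage and Kupffer cell markers (12 of 13, adjusted p = 0.0113) and bile acid and xenobiotic metabolism (22 of 31, adjusted p = 0.0318), while fibroblast and stellate cell markers fell (9 of 11 lower, adjusted p = 0.0343). With an estimated correlation these gave adjusted p = 0.55, 0.45, 0.39, 0.55 and 0.45. Of 100 random splits of the early livers, 26, 18, 3, 11 and 20 gave a camera p as small, the real split included. Random groupings of the same animals thus often gave such a p, least often for macrophage markers. FASN, the fatty acid synthase, was at 27.3 ± 23.2 FPKM against 8.3 ± 1.96 (n = 5 each), ACACA, the acetyl-CoA carboxylase that feeds it, at 21.8 ± 6.2 against 10.2 ± 4.78, and the complement gene C1QC at 289 ± 29.2 against 223 ± 35.1. PDGFRB, a receptor of stellate cells, was at 13.5 ± 3.79 against 21 ± 4.27 FPKM. Oxidative phosphorylation no longer passed without control animal 3 (adjusted p = 0.0793) or 4 (0.0891), fatty acid synthesis without control 4 (0.103) or low-protein 2 (0.249), and macrophage markers without control 4 (0.0891). The bile acid list no longer passed without control animals 3 (0.0538), 4 (0.0891) or 5 (0.0987) or low-protein animals 2 (0.124) or 4 (0.109), and the fibroblast list without control animals 1 (0.171), 3 (0.108) or 4 (0.201) or low-protein animals 1 (0.0758), 4 (0.107) or 5 (0.119). After each library's trend over exonic length was removed, oxidative phosphorylation had adjusted p = 0.429. With the share of unspliced transcripts as a covariate, bile acid metabolism had 0.104 and fibroblast markers 0.193, and from the mean over consensus exonic bases bile acid metabolism had 0.144. Without control animal 4 the interferon list, which was not called, rose at adjusted p = 0.00113. It passed in the opposite direction, lower on low protein, without control animal 2 (0.00154) or 5 (0.04) or low-protein animal 2 (0.014).

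Among genes fixed in advance in early liver, IGFBP2, a binding protein of insulin-like growth factors, was at 206 ± 58.8 FPKM against 91.6 ± 31.9 (n = 5 each; log2 change 1.19 ± 0.32, limma adjusted p = 0.62). Other genes were picked for their small p. ANGPTL8, an insulin-responsive hepatokine, was at 6.94 ± 3.43 against 1.69 ± 0.489, with limma adjusted p = 0.34, and at 0.0165 without low-protein animal 5. TOP3A, a topoisomerase, was at 17.7 ± 3.37 against 2.95 ± 4.65, with limma adjusted p = 0.34, and at 0.041 without control animal 5. The adjacent genes MRPL47 (3.26 ± 0.344 against 11.8 ± 3.09 FPKM) and NDUFB5 (38.1 ± 15.7 against 20 ± 12.7) lay in opposite directions, and their values are uncertain because transcripts of neighbouring genes can be assembled together. Of the genes fixed in advance, IGF1 and the urea cycle enzyme CPS1 differed by less than the spread between animals (log2 changes −0.23 ± 0.41 and −0.19 ± 0.47). The asparagine synthetase ASNS was at 2.24 ± 0.916 against 1.47 ± 0.234 FPKM. Amino acid deprivation genes as a list did not pass (20 of 26 higher, camera adjusted p = 0.083), but did without control animal 2 (0.0344) or low-protein animal 3 (0.01). They also passed from consensus bases (0.0181) and the longest assembled gene (0.0475). Extracellular matrix genes, not called in the main fit (0.15), passed from those 2 gene values (0.000105 and 0.00104). They also passed without control animal 2 (0.0446) or 5 (0.0035) or low-protein animal 3 (0.00795). Of 100 random splits, 9 and 58 gave a camera p as small for these lists in the main fit. FGF21 was assembled in 9 of 19 livers and was not tested. The number of genes called was 1 without control animal 5 and 2 without low-protein animal 5.

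**Figure D1:**
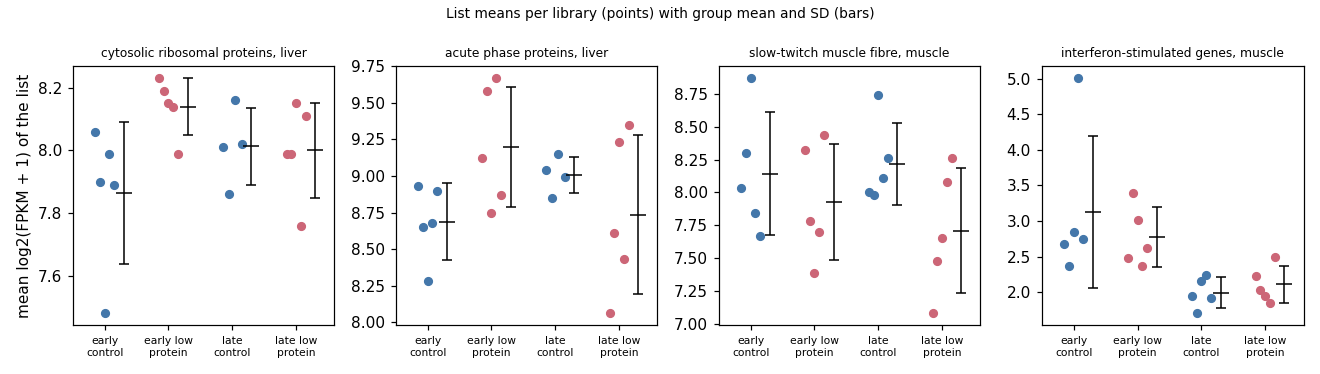
Mean log2(FPKM + 1) of 4 gene lists (vertical axis) in each library (points), by group, with group mean and SD (bars). Ribosomal protein means were 7.99 to 8.23 in early low-protein livers against 7.48 to 8.06 in early controls, and 1 early control muscle reached 5.01 for interferon-stimulated genes where the other early muscles reached at most 3.39.

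The same diet comparison was made in liver at the end of the growing period. GPR180, which encodes a G protein-coupled receptor-like membrane protein (chromosome 11, 63720048 to 63764720, Sscrofa11.1), was the single gene called of 11989. It fell by 1.64 ± 0.22 on the log2 scale, from 11.5 ± 2.91 FPKM (n = 4) to 2.99 ± 0.819 (n = 5), with limma adjusted p = 0.0056 and lower in 5 of 5 low-protein animals than the control mean. The change was −0.13 (adjusted p = 0.666) from the mean over consensus exonic bases and −0.23 (0.639) from the single longest assembled gene. CYP7A1, the rate-limiting enzyme of bile acid synthesis, was at 3.38 ± 4.5 FPKM (n = 5) against 26.4 ± 16.5 (n = 4), a log2 change of −3.05 ± 0.61 with limma adjusted p = 0.13. It reached adjusted p = 0.0367 without low-protein animal 3 and 0.0355 with library weights. Without transcripts under 300 bp its late change was −2.95 (limma adjusted p = 0.121), and its early change lay the other way at 1.65 (0.74). The clock genes DBP (15.6 ± 13.1 against 49.8 ± 19.5 FPKM) and PER3 (14.4 ± 2.96 against 28 ± 5.79) lay below the control mean in all 5 low-protein animals, as did OTC of the urea cycle (112 ± 41.2 against 182 ± 11.7). MARCO, a scavenger receptor of macrophages, was at 3.91 ± 2.58 against 10.9 ± 4.15, whereas the macrophage gene VSIG4 was at 18.1 ± 3.12 against 11.7 ± 1.61.

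In the main fit no list passed in late liver: by camera, amino acid catabolism (31 of 48 members lower), the circadian clock (13 of 17 lower) and macrophage markers (11 of 13 higher) each had adjusted p = 0.0579, and bile acid metabolism (24 of 31 lower) 0.0598. Without single libraries these lists passed: amino acid catabolism without control animal 4 (0.0273) or low-protein animal 3 (0.00432) or 5 (0.0403), the clock without low-protein 3 (0.0188), macrophage markers without control 2 (0.0101) or 4 (0.0273) or low-protein 4 (0.0471), and bile acid metabolism without control 4 (0.0344) or low-protein 3 (0.00432) or 5 (0.0424). Respectively 0, 2, 1 and 2 members of these lists passed when adjusted over the list alone. Of 100 random splits of the late livers, 18, 4, 24 and 36 gave a camera p as small in the main fit, the real split included. Random groupings of the same animals thus often gave such a p, least often for the clock. With all libraries these lists also passed by camera under other settings. From consensus bases amino acid catabolism had 0.00938 and the others 0.0317. From the longest assembled gene bile acid metabolism had 0.0227 and the others 0.0128. From FPKM as deposited all but macrophage markers had 0.0323. Without transcripts under 300 bp all but the clock had 0.0233. With the unspliced share as a covariate amino acid catabolism had 0.00191 and bile acid metabolism 0.0125. In late liver 1268 genes had an unadjusted p under 0.05 where chance gives 599, and 10 passed an adjusted p of 0.1. The count of genes called was 10 without control animal 5, 3 without control 4, 7 without low-protein 3 and 2 without low-protein 2.

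Over both times together, low-protein livers had higher ribosomal protein transcripts (58 of 76 members, median log2 change 0.11) and macrophage markers (11 of 13, median 0.24), with C1QC at 243 ± 54.9 FPKM (n = 10) against 189 ± 51.4 (n = 9). Both lists rose by camera (adjusted p = 9.92e-05 and 0.000242; adjusted p = 0.86 and 0.21 with an estimated correlation). Amino acid deprivation genes (20 of 26 higher) and chaperones (19 of 24 higher) passed at adjusted p = 0.0401 each, and at adjusted p = 0.2 and adjusted p = 0.86 with an estimated correlation. From consensus bases, the longest assembled gene and transcripts of at least 300 bp, the first had 0.0664, 0.106 and 0.0511 and the second 0.142, 0.115 and 0.0511, and with the unspliced share as a covariate 0.23 and 0.62. IGFBP1, a fasting-induced binding protein and an amino acid deprivation target, was at 241 ± 239 against 170 ± 262 FPKM. Limma called 0 genes, with 683 at an unadjusted p under 0.05, and 1 gene without early low-protein animal 4, late control 5 or late low-protein 2. No list had a member that passed when adjusted over the list alone (0 of each). The amino acid deprivation list no longer passed without any of 8 single livers and the chaperone list without any of 10. The first was at adjusted p = 0.0793 without early control 1, 0.0555 without early control 4, 0.0619, 0.0518 and 0.148 without early low-protein 1, 2 and 4, 0.0852 and 0.102 without late control 1 and 5, and 0.0632 without late low-protein 5. The chaperone list was at 0.0793 and 0.266 without early control 1 and 3, 0.149 and 0.152 without early low-protein 2 and 4, 0.092, 0.138 and 0.0548 without late control 1, 2 and 4, and 0.0583, 0.0989 and 0.0864 without late low-protein 2, 3 and 5. With the length trend removed, the ribosomal list gave adjusted p = 0.0554, amino acid deprivation 0.0688 and chaperones 0.0952.

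Whether the diet effect in liver differed between the times was tested as an interaction. The low-protein change of ribosomal protein transcripts was lower late than early (60 of 76 members lower, median difference −0.43, camera adjusted p = 1.66e-05), as was that of acute phase proteins (13 of 15, 0.0046), bile acid metabolism (24 of 31, 0.00493), chaperones (20 of 24, 0.00493), fatty acid synthesis (13 of 21, 0.00981), the circadian clock (13 of 17, 0.0215) and oxidative phosphorylation (34 of 47, 0.043). With an estimated correlation none passed (adjusted p = 0.53 for the first 6 and 0.85 for the last). The median log2 change on low protein was positive early and negative late in each: 0.36 and −0.08 for ribosomal proteins, 0.59 and −0.34 for acute phase proteins, 0.31 and −0.23 for bile acid metabolism and 0.26 and −0.15 for chaperones. It was 0.32 and −0.35 for fatty acid synthesis, 0.2 and −0.23 for the clock and 0.21 and −0.04 for oxidative phosphorylation. In the main fit with all libraries no list passed late, but without late low-protein animal 3 bile acid metabolism (0.00432) and the clock (0.0188) did. Both also passed late with all libraries under some other settings, as given above. Acute phase proteins passed late from consensus bases (0.0317) and with the unspliced share as a covariate (0.0125). Fatty acid synthesis did from the longest assembled gene (0.0283). For either list, 36 of 100 random splits of the late livers gave a camera p as small in the main fit. The members that passed lower when adjusted over the list alone were 4 acute phase, 2 bile acid, 2 chaperone and 2 clock genes, with 1 chaperone gene higher and 0 of the others. GPR180 was again the single gene called (difference −2.01 ± 0.3, limma adjusted p = 0.028), with 1358 genes at an unadjusted p under 0.05. From the mean over consensus exonic bases the difference was −0.26 (adjusted p = 0.473), from the single longest assembled gene −0.6 (0.312), from FPKM as deposited −1.92 (0.0785) and with a pseudocount of 0.1 −2.42 (0.0612). Its early means were 2.23 ± 0.97 FPKM in controls and 3.09 ± 0.664 on low protein. The count fell to 0 without early control 1, 2, 3 or 4, early low-protein 3 or 4, late control 2 or 4, or late low-protein 1 or 2, where GPR180 had adjusted p between 0.0648 and 0.0952. It was 2 without early low-protein 1, 2 or 5, 3 without late control 5 and 5 without late low-protein 3. The clock list no longer passed without early control 4 (0.058) or 5 (0.0535) or early low-protein 3 (0.0666), the fatty acid list without early low-protein 2 (0.075) and the chaperone list without late control 5 (0.0606). Oxidative phosphorylation no longer passed without early control 1 (0.0611), 3 (0.234) or 4 (0.209), early low-protein 1 (0.159), 2 (0.0856) or 4 (0.103), late control 1 (0.124), 2 (0.0976) or 5 (0.0669), or late low-protein 4 (0.12) or 5 (0.0841), nor from FPKM as deposited (0.0931) or with the length trend removed (0.547). With unassembled genes set to 0 it had 0.0548 and acute phase proteins 0.0678, and without transcripts under 300 bp the clock list had 0.0571. Without early control 4 the interferon list, not called here, had adjusted p = 0.0315. Amino acid catabolism, also not called here, passed by camera with all libraries in some other settings. Its adjusted p was 0.0287 from FPKM as deposited, 0.0156 from consensus bases, 0.0407 from the longest assembled gene and 0.0245 with the unspliced share as a covariate.

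In muscle at day 20, interferon-stimulated genes, the antiviral response, were lower on the low-protein diet in 28 of 30 members, with a median log2 change of −0.41. BST2 was at 6.36 ± 2.33 FPKM against 13.3 ± 5.22, and GBP2 at 3.15 ± 0.513 against 7.96 ± 9.13 (n = 5 each). The list fell by camera (adjusted p = 0.002; adjusted p = 0.87 with an estimated correlation), but without control animal 4 it lay higher instead, with adjusted p = 0.302. Of 100 random splits of the early muscles, 71 gave a camera p as small, the real split included. INSIG1, a regulator of sterol synthesis, was at 2.59 ± 0.306 against 5.34 ± 1.54 FPKM and LIMCH1, an actin-associated protein, at 20.1 ± 1.95 against 31.7 ± 2.03 (n = 5 each), with limma adjusted p = 0.21 and 0.22. The ubiquitin ligase FBXO32, a marker of muscle protein breakdown, was at 18.6 ± 16.2 against 23.7 ± 13.9, and the growth inhibitor MSTN at 6.71 ± 1.78 against 8.14 ± 1.8. Limma called 0 of 10910 genes, and 457 had an unadjusted p under 0.05 where chance gives 546. When adjusted over the list alone, 0 interferon genes passed. Ribosomal proteins and aminoacyl-tRNA synthetases were not called in the main fit (camera adjusted p = 0.0847 each). From consensus bases they passed at 0.00389 and 0.00745, and from the longest assembled gene at 0.00437 and 0.00626. Ribosomal proteins also passed without transcripts under 300 bp (0.0373). Of 100 random splits, 22 and 24 gave a camera p as small for these lists in the main fit.

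In late muscle, slow-twitch fibre genes were lower on the low-protein diet in 14 of 14 members, with a median log2 change of −0.48. The slow myosin MYH7 was at 979 ± 320 FPKM against 1430 ± 215, troponin TNNC1 at 841 ± 211 against 1230 ± 171 and tropomyosin TPM3 at 568 ± 202 against 786 ± 108 (n = 5 each). Chaperones were lower in 17 of 23 members, with HSPA5 at 22 ± 1.02 against 29 ± 2.23 and PDIA6 at 12.1 ± 1.33 against 15.8 ± 3.7. The slow-twitch list fell with camera adjusted p = 1.61e-05 and the chaperone list with 0.0116, and adjusted p = 0.98 for each with an estimated correlation. Random splits of the early muscles gave an unadjusted camera p as small as 5.12e-16 for slow-twitch genes and 9.17e-11 for chaperones. Small camera p-values of these lists could thus arise from differences between animals. ADAMTS8, a secreted protease, was at 6.23 ± 6.2 against 1.14 ± 0.361 FPKM (limma adjusted p = 0.54), and FBXO32 at 52.3 ± 22.9 against 37.6 ± 4.3. The fast myosin MYH4 was assembled in 0 of 20 muscles and was not tested. Limma called 0 genes, with 688 at an unadjusted p under 0.05, and 0 members of either list passed when adjusted over the list alone. The count was 1 without control animal 3 or low-protein 2 or 3. The chaperone list no longer passed without control 3 (0.112) or low-protein 4 (0.0692), from FPKM as deposited (0.0529), or with the unspliced share as a covariate (0.256).

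Over both times, slow-twitch genes (14 of 14 members lower, median −0.3) and chaperones (19 of 23 lower) fell in low-protein muscle (camera adjusted p = 8.51e-05 and 0.00196; adjusted p = 0.95 for each with an estimated correlation). TNNT1, a slow troponin, was at 768 ± 230 FPKM (n = 10) against 1070 ± 375 (n = 10), and the chaperone HYOU1 at 3.62 ± 0.436 against 6.25 ± 3.16. Limma called 0 genes, with 637 at an unadjusted p under 0.05, and 1 without late low-protein animal 3, and 0 members passed when adjusted over the list alone. Without early control 5 the chaperone list had adjusted p = 0.114. Between the times, 4 lists differed in their diet effect by camera: interferon-stimulated genes (27 of 30 members higher late, adjusted p = 0.0124), aminoacyl-tRNA synthetases, which charge tRNAs (17 of 20 lower, 0.0124), ribosomal proteins (54 of 78 lower, 0.0178) and slow-twitch genes (13 of 14 lower, 0.0397). With an estimated correlation each had adjusted p = 0.9. Limma called 0 genes for this difference, with 481 at an unadjusted p under 0.05 and 0 members adjusted over the list alone, and 1 without early control 5, early low-protein 3 or late control 3, and 2 without late low-protein 3. The interferon difference had adjusted p = 0.894 in the other direction without early control 4, 0.0605 without early low-protein 1 and 0.0502 without late control 2, and the synthetase difference 0.0811 without early control 2. The ribosomal difference no longer passed without early control 1 (0.0674) or 3 (0.073), early low-protein 1 (0.0856), late control 1 (0.131) or 2 (0.0502), or late low-protein 1 (0.136) or 2 (0.0911). The slow-twitch difference no longer passed without early control 1 (0.0869), 4 (0.178) or 5 (0.288), early low-protein 1 (0.159) or 5 (0.243), late control 3 (0.21) or 5 (0.0719), or late low-protein 1 (0.314) or 2 (0.136). With the length trend removed these 2 lists had 0.0973 and 0.0791.

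Whether liver and muscle differed in their diet effect was tested on 9820 genes measured in each tissue. Limma called 0 genes early, with 581 at an unadjusted p under 0.05, and 0 late, with 890, where chance gives 491. The early count was 2 without liver control animal 5, and the late count 6 without liver low-protein 5 and 1 without liver control 4. Across genes, which are not independent replicates, the early and late diet changes of liver had a Pearson correlation of −0.14, a value that 4 of 100 splits of the samples reached or passed in size. Without any single liver other than early low-protein 1 or 5 or late low-protein 3, that is for 16 of 19 libraries, it no longer stood apart from the splits. Its values without each of the 19 libraries were −0.19 to −0.094. In muscle it was 0.11 (15 of 100 splits), and 0.026 without early control 5. Between liver and muscle it was −0.034 early (57 of 100), and 0.0024 without liver early low-protein 3. Late it was 0.06 (23 of 100), with 0.031 without muscle control 4, 0.093 without muscle control 3 and 0.091 without liver low-protein 4. These 4 correlations were not adjusted for their number.

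Late and early animals were then compared over both diets, a contrast in which slaughter batch, slaughter day and growth stage are the same thing. The labels call the early and late groups batches, so a difference in handling or library preparation between the batches and an effect of time cannot be told apart, because each time was 1 batch. In liver, IGFBP1 fell from 343 ± 279 FPKM (n = 10) to 57.7 ± 23.4 (n = 9), a log2 change of −2.28 ± 0.4, and the insulin receptor substrate IRS2 from 41.4 ± 35.2 to 6.5 ± 1.92 (−2.24 ± 0.28), with limma adjusted p = 0.006 and 0.00057. Matrix genes were lower in 22 of 24 members (median −0.55), with COL1A1, a fibrillar collagen, at 18.9 ± 9.37 against 60.8 ± 38.2 and elastin ELN at 2.92 ± 0.596 against 10.1 ± 5.07. Metabolic enzymes were among the genes that rose: CYP8B1, an enzyme of bile acid synthesis, went from 2.56 ± 3.14 to 14.7 ± 6.29 FPKM (2.4 ± 0.35), the cytochrome CYP2A19 from 228 ± 101 to 757 ± 308, and the thiolase ACAA2 from 147 ± 41.9 to 337 ± 125. Amino acid catabolism and the urea cycle had 40 of 48 members higher, with ALDH4A1 of proline breakdown at 62.5 ± 19.1 against 35.3 ± 7.93, and fatty acid oxidation 22 of 29. In all, limma called 471 of 11989 genes, 228 higher and 243 lower (119 and 257 from FPKM as deposited).

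Liver lists that changed with time by camera were the matrix (adjusted p = 2.53e-07), amino acid catabolism (4.89e-05), fatty acid oxidation (0.000475), the proteasome (30 of 37 higher, 0.000475), oxidative phosphorylation (37 of 47 higher, 0.0012), bile acid metabolism (25 of 31 higher, 0.0012), interferon genes (29 of 30 lower, 0.0012), the cell cycle (19 of 21 lower, 0.00288), macrophage markers (9 of 13 lower, 0.00678) and cholesterol synthesis (14 of 22 higher, 0.032). With an estimated correlation none passed (adjusted p = 0.34 for the matrix, amino acid, fatty acid oxidation, bile acid, cell cycle and macrophage lists, 0.47 for the proteasome and oxidative phosphorylation, 0.61 for interferon genes and 0.52 for cholesterol synthesis). Members in the list's direction that passed when adjusted over the list alone were 15 matrix, 9 amino acid, 9 fatty acid oxidation, 6 proteasome, 2 oxidative phosphorylation, 8 bile acid, 4 interferon, 1 cell cycle, 6 macrophage and 5 cholesterol genes, against 5, 5, 6, 1, 2, 3, 0, 1, 5 and 1 over all genes. Against the list's direction, 2 bile acid genes and 1 macrophage gene passed (1 and 1 over all genes). For the interferon list, early control animal 4 stood far above the other early controls and raised the early mean. Its list mean was 6.4 on the log2(FPKM + 1) scale, where that group had 4.29 ± 1.24. The cholesterol list no longer passed without early control 5 (0.0512), early low-protein 1 (0.1) or 4 (0.0596), late control 4 (0.0722) or late low-protein 2 (0.0614) or 4 (0.144), nor from consensus bases (0.256), the longest assembled gene (0.168) or with the length trend removed (0.0535, where oxidative phosphorylation had 0.0713). Unspliced transcripts made up 42.7 ± 3.55% of early and 37.1 ± 3.2% of late liver libraries, and with that share as a covariate 2 of the 471 genes still passed while all 471 kept their sign. The log2 change was then −0.66 for COL1A1 (limma adjusted p = 0.616), 1.55 for CYP8B1 (0.203) and −2.38 for IGFBP1 (0.194), and the interferon, oxidative phosphorylation and proteasome lists gave adjusted p = 0.202, 0.439 and 0.472.

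The largest liver changes included genes whose FPKM stood mainly in transcripts under 300 bp: SEC16B (3.62 ± 0.94), SLC5A1 (3.29 ± 0.55) and VPS13C (−3.4 ± 0.89), with 97.3%, 93.9% and 98.8% of their FPKM there. Without those transcripts the log2 change was −0.45 for SLC5A1 (limma adjusted p = 0.157), 0.56 for VPS13C (0.153) and 0.59 for SEC16B (0.0461). From the single longest assembled gene it was −0.37 for IRS2 (0.334) and −0.54 for ACAA1 (0.692), a thiolase that was 0.57 ± 0.13 higher late. Single libraries ended several calls. SEC16B no longer passed without early control 1, 2, 3 or 4, early low-protein 1, 3 or 5, late control 1, 2 or 5 or late low-protein 3 or 5 (12 libraries, adjusted p = 0.0519 to 0.0723). VPS13C no longer passed without early control 1, 2 or 3, early low-protein 3, 4 or 5, late control 2 or 4 or late low-protein 1, 3, 4 or 5 (12 libraries, 0.051 to 0.0726). NDUFS4 of complex I no longer passed without early control 1, 3 or 4, early low-protein 1 or 5, late control 1, 2, 4 or 5 or late low-protein 3, 4 or 5 (12 libraries, 0.0514 to 0.0723). SDHC of complex II no longer passed without early control 1 or 3, early low-protein 1, 3 or 5, late control 1, 2 or 4 or late low-protein 2 or 3 (10 libraries, 0.0511 to 0.0724). GCAT of threonine breakdown no longer passed without early low-protein 3 or 5, late control 1, 2 or 4 or late low-protein 3 or 5 (7 libraries, 0.051 to 0.054). The count of genes called was 233 and 251 without late control 1 and 2, 243 and 284 without late low-protein 3 and 5, 269 and 281 without early low-protein 5 and 3, 283, 270 and 311 without early control 1, 3 and 4, and 828 without early control 5.

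**Figure D2:**
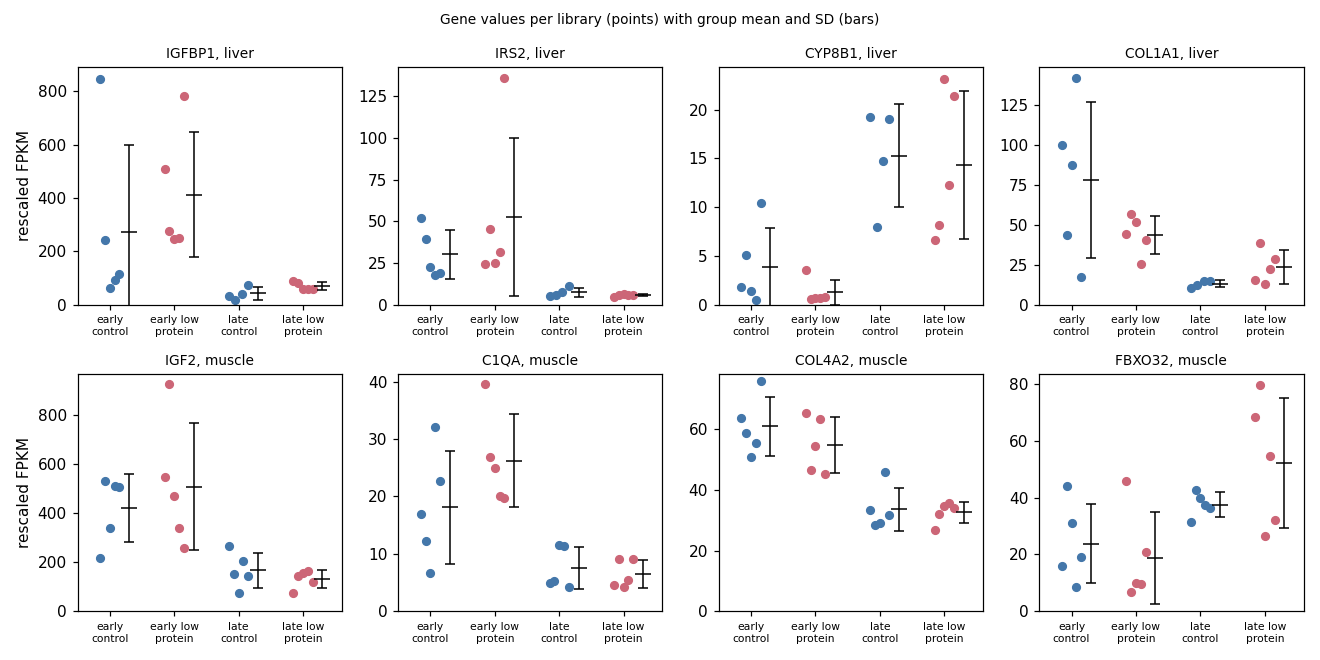
Rescaled FPKM (vertical axis) of 4 liver and 4 muscle genes, picked after their values were seen, in each library (points) with group mean and SD (bars). IRS2 lay between 17.8 and 136 in early livers and between 4.73 and 11.2 in late ones, and COL4A2 between 45.1 and 75.9 in early muscles and between 26.9 and 45.9 in late ones.

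In muscle, IGF2, an insulin-like growth factor, fell from 465 ± 201 FPKM (n = 10) to 150 ± 56.6 (n = 10), a log2 change of −1.61 ± 0.25 (limma adjusted p = 0.00065). Matrix genes were lower in 25 of 26 members, with the basement membrane collagens COL4A2 at 33.2 ± 5.3 against 57.9 ± 9.45 and COL4A1 at 60.7 ± 17 against 95.7 ± 14.2. Interferon-stimulated genes were lower in 29 of 30 members, among them GBP1 (2.89 ± 0.694 against 10.5 ± 5.92) and IFI6 (18.3 ± 5.98 against 64.7 ± 64.4). Early control animal 4 stood far above the other early muscles for this list, and without it the log2 change of IFI6 was −1.25 instead of −1.5, that of GBP1 −1.31 instead of −1.46, and the list had adjusted p = 4.96e-10. Markers of macrophages (9 of 9 members lower; C1QA at 6.98 ± 2.97 against 22.2 ± 9.5), endothelium (12 of 12; CDH5 at 10.7 ± 1.65 against 17.4 ± 4.87) and fibroblasts (8 of 8; PDGFRA at 3.24 ± 0.951 against 4.83 ± 1.02) were lower too. Genes of muscle protein breakdown and autophagy were higher in 20 of 26 members, with FBXO32 at 44.9 ± 17.4 against 21.2 ± 14.5 and FBXO31, another ubiquitin ligase subunit, at 49.9 ± 5.7 against 37.3 ± 5.65. Among the 6 highest changes, the immediate early gene FOS went from 27.9 ± 30.1 to 61.1 ± 14.8 and the chaperone HSPA6, which has close copies, from 5.37 ± 8.08 to 19.6 ± 13.2.

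Limma called 1264 of 10910 muscle genes, 577 higher and 687 lower. By camera the matrix (adjusted p = 4.18e-09), interferon (4.62e-09), macrophage (9.02e-07), endothelial (9.02e-07) and fibroblast (0.00407) lists fell and protein breakdown rose (0.000863), with adjusted p = 0.26, 0.38, 0.2, 0.06, 0.26 and 0.26 with an estimated correlation. When adjusted over the list alone, 16 matrix, 18 interferon, 8 macrophage, 8 endothelial and 3 fibroblast genes passed, against 14, 14, 5, 7 and 2 over all genes, and 11 protein breakdown genes passed higher and 1 lower, against 6 and 0. Unspliced transcripts made up 26.3 ± 4.27% of early and 21.8 ± 2.85% of late muscle libraries. With that share as a covariate 620 of the 1264 genes still passed while all 1264 kept their sign (median size of the log2 change 0.51 without and 0.5 with it). IGF2, COL4A2, GBP1 and C1QA were among those that passed. FBXO32 did not (1.21, limma adjusted p = 0.0689), nor did PDGFRA (−0.52, 0.0582), FOS (1.51, 0.157), HSPA6 (1.67, 0.176), STBD1 (1.94, 0.192), HSPA1L (1.01, 0.306), TOX (4.61, 0.223) or CEP250 (−3.94, 0.282). Of the 644 genes that no longer passed, 480 had a smaller change with the covariate. Their median size of the log2 change was 0.48 without it and 0.41 with it, and their median standard error 0.13 and 0.16. The 620 that still passed had a median of 0.54 without and 0.6 with it. From the consensus bases the log2 change of FBXO32 was 0.87 (0.112). TOX (7.51 ± 1.99) and CEP250 (−6.29 ± 1.83) had 100% and 99.9% of their FPKM in transcripts under 300 bp, and for CEP250 the log2 change was 0.06 (0.848) without those. CEP250 no longer passed without early control 2 or 3, early low-protein 3, 4 or 5 or late control 2 (6 libraries, adjusted p = 0.0521 to 0.0571). STBD1 of glycogen handling (2.46 ± 0.72) no longer passed without early control 3 or 4, late control 1, 2 or 5 or late low-protein 1 (6 libraries, 0.0518 to 0.0721). The chaperone HSPA1L (1.56 ± 0.48), which has close copies, no longer passed without early control 1, 2, 3 or 4, early low-protein 1, 2, 3 or 5, late control 1, 4 or 5 or late low-protein 2, 4 or 5 (14 libraries, 0.0507 to 0.0752). MFAP5 of fibroblasts (−0.47 ± 0.15) no longer passed without early control 1, 4 or 5, early low-protein 1, 2 or 3, late control 1, 2, 3 or 5 or late low-protein 1, 2 or 4 (13 libraries, 0.0634 to 0.0862).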

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

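The tests in this part were set before their results were seen on the gene values used here, but list results had been seen on another gene value, and the length correlations of single libraries had been seen before the length test.

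A lone animal stood apart from the other 4 of its group, or the other 3 where n = 4, in 31 groups of named genes and 1 group of a gene list, of 505 examined, where chance gives about 25. Named genes that are not reported were left out of this count, a choice made after their values were seen. The chance figure does not allow for that choice. The value given is the gap to the nearest animal divided by the range of the group. The clearest pattern was control animal 4 in early muscle, which was highest for GBP2 (0.811), CXCL10 (0.742), MX1 (0.785) and IFI6 (0.75) and for the mean of the interferon list (0.819). In early control liver, animal 3 was lowest for RPLP0 (0.763) and IGF1 (0.721), animal 5 highest for SEC16B (0.876) and animal 1 highest for SLC5A1 (0.856). In early low-protein liver, animal 5 was highest for NDUFB5 (0.713) and lowest for MARCO (0.718) and ELN (0.718), animal 4 highest for C1QC (0.742) and animal 1 highest for CYP8B1 (0.896). In late liver, control animal 4 was lowest for VPS13C (0.864), and in the low-protein group animal 5 was lowest for RPS18 (0.79), animal 4 lowest for CYP2A19 (0.73), and animal 2 highest for SEC16B (0.837) and VPS13C (0.867) and lowest for NDUFS4 (0.825). In early low-protein muscle, animal 5 was highest for CACUL1 (0.719) and lowest for MSTN (0.737) and TOX (0.904), and animal 1 lowest for STBD1 (0.773). Early control muscle 5 was highest for PDIA6 (0.841). In late control muscle, animal 3 was lowest for ASNS (0.907), animal 4 highest for SCD (0.75) and CDH5 (0.747), animal 5 highest for HSPA6 (0.722) and animal 2 lowest for MX1 (0.719). In late low-protein muscle, animal 1 was highest for ADAMTS8 (0.772) and lowest for HSPA6 (0.81).

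The diet effect differed between the times, by a test of the difference itself, for GPR180 in liver (−2.01, but −0.26 from consensus bases and −0.6 from the longest assembled gene, where it no longer passed) and for 11 lists by camera with a preset correlation. In liver these were ribosomal proteins (adjusted p = 1.66e-05), acute phase proteins (0.0046), bile acid metabolism (0.00493), chaperones (0.00493), fatty acid synthesis (0.00981), the clock (0.0215) and oxidative phosphorylation (0.043). In muscle they were aminoacyl-tRNA synthetases (0.0124), interferon genes (0.0124), ribosomal proteins (0.0178) and slow-twitch genes (0.0397). None passed with an estimated correlation, where the adjusted p was 0.53 to 0.9, and without any of 10 single libraries GPR180 did not pass.

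The higher ribosomal protein transcripts of early low-protein liver (median log2 change 0.36) were weighed against technical explanations. After each library's trend over exonic length was removed the median was 0.23 (adjusted p = 1e-05), and with the unspliced share as a covariate it was 0.34 (adjusted p = 2.8e-11), each at least 50% of the change, which argues against either as the whole cause, although the drop with length, 0.36 to 0.23, was within the spread over members (SD 0.46). Of 100 splits of the 10 early livers, 2 gave a list p as small as the real 7.72e-14, the real one included, and the smallest other was 4.22e-17, and the real p was the smallest of the lists tested, so this count is weak evidence against chance. A diet effect on this list is a hypothesis that may hold, and it stays open beside sampling of animals, because the list did not pass with an estimated correlation.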

How the results depend on the processing

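The gene values other than the planned sum, unassembled genes set to 0, genes with a value in every library, the length trend and the unspliced share were chosen after the data were seen. Of 47 named genes called, 805 of 907 values without 1 library and 632 of 695 under other settings kept their direction and side of the threshold, and of 44 lists called, 669 of 749 and 463 of 572 did. The cause was not tested for the differences below. Genes called for the late diet in liver (1) numbered 26 with library weights, 5 with only the groups compared, 10 at an adjusted p of 0.1, 0 from consensus bases, 0 from the longest assembled gene and 3 with unassembled genes at 0. For diet by time in liver (1) they were 0 with a pseudocount of 0.1, from FPKM as deposited, from consensus bases and from the longest gene, 2 without transcripts under 300 bp and 3 with unassembled genes at 0. For liver time (471) they were 1209 at 0.1, 1199 from consensus bases, 714 from the longest gene and 2 with the unspliced share, and for muscle time (1264) 2563, 2091 and 752 from consensus bases, the longest gene and the unspliced share. Where limma called 0, it called 1 in early liver with only the groups compared, 1 in liver over both times with unassembled genes at 0, and 1 for diet by time in muscle with a pseudocount of 0.1, from FPKM as deposited, with library weights, at 0.1 and with the length trend removed. For the late diet by tissue it called 1 from FPKM as deposited, with library weights and from the longest gene and 2 with unassembled genes at 0, and for the early diet by tissue 1 from the longest gene. Some directions turned: VPS13C was 0.08, 0.01 and 0.56 from consensus bases, the longest gene and transcripts of at least 300 bp, ACAA1 −0.54 from the longest gene, and SLC5A1 −0.45 and CEP250 0.06 from transcripts of at least 300 bp, and slow-twitch genes turned over time in muscle (adjusted p = 0.0449) with the unspliced share. Individual numbers within a tissue showed no pairing of the samples on the planned gene value (correlations −0.16 to 0.035). That value also showed no pairing of liver with muscle where the sum from 300 bp did, so pairing by number is not excluded. As a replicate block, the number gave 2 calls in late liver, 216 for liver time and 0 for diet by time in liver, and the late liver lists of amino acid catabolism, bile acid metabolism and the clock had 0.046, 0.046 and 0.0142, fatty acid synthesis and red blood cell markers over time in liver 0.0201 and 0.0493 and the cell cycle over time in muscle 0.0301, while oxidative phosphorylation for diet by time in liver had 0.139 and slow-twitch genes for diet by time in muscle 0.0576. Without 1 library in turn, calls ranged from 0 to 2 in early liver, 1 to 10 in late liver, 0 to 1 over both times, 233 to 828 for time and 0 to 5 for diet by time. In muscle they ranged from 0 to 0 early, 0 to 1 late, 0 to 1 over both times, 954 to 1275 for time and 0 to 2 for diet by time, and by tissue from 0 to 2 early and 0 to 6 late. The adjusted p of the interferon list ranged from 0.00113 to 0.817 in early liver, 0.0315 to 0.98 for diet by time in liver, 2.24e-06 to 0.302 in early muscle and 0.000157 to 0.894 for diet by time in muscle. Correlations across genes ranged from −0.19 to −0.094 (liver), 0.026 to 0.15 (muscle), −0.055 to 0.0024 (early, between tissues) and 0.031 to 0.093 (late). The filter at a mean FPKM of 0.1 and no filter tested the same genes, since a value was needed in 3 libraries of each group, and an analysis restricted to reference transcripts was not run. Depth was known only as coverage at 1 FPKM.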

Other observations

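The tests of the main cell type, of the size of the change and of the matrix and cell type lists were chosen after the result was seen, and the muscle index genes FBXO32 and TRIM63 were picked after their values were seen; the other tests were set before, on another gene value.

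Control animal 4 of the early groups had the highest mean of interferon-stimulated genes in liver, 6.4 on the log2(FPKM + 1) scale where the other 4 control livers lay between 3.18 and 4.16, and also in muscle, 5.01 where the others lay between 2.36 and 2.84. The same animal number thus stood apart in each tissue, and no cause was tested.

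Other splits of the samples were counted for each number of genes called, 100 splits per comparison with the real one included. For time, 1 of 100 splits called as many genes in liver (471, highest other 3) and 1 of 100 in muscle (1264, highest other 2). This argues against chance, and 1 of 100 is the least that this count can give. For the late diet in liver, 15 of 100 called as many (1, highest other 8), and for diet by time in liver 15 of 100 (1, highest other 2), so chance was not excluded for GPR180. With 0 genes called, all 100 splits called as many: the highest other was 12 in early liver, 8 in liver over both times, 5, 2, 4 and 2 in muscle early, late, over both times and by time, and 9 and 8 by tissue early and late.

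Lower matrix and cell type markers in late animals were weighed against tissue make-up: a higher share of the main cell type would lower all other types alike. In liver the lists differed (macrophage −0.5, fibroblast −0.28, bile duct −0.054, lymphocyte −0.014, endothelial 0.1, adipocyte 0.43, red blood cell 0.45, permutation p = 0.0045). That permutation shuffled genes, which are not independent replicates. The medians lay further apart than the largest SD over members (0.63) only with the adipocyte or red blood cell list. Neither was called over time (camera adjusted p = 0.078 and 0.0812). The test therefore cannot decide, and both a higher share of the main cell type and a change in single types stay open in liver. In muscle all 4 lists fell (macrophage −0.64, endothelial −0.5, fibroblast −0.36, adipocyte −0.35, permutation p = 0.017), with gaps within the SD of the macrophage members (0.44), so it stays open there. With the unspliced share, which itself differed with time, as a covariate, 2 of 471 liver genes stayed called (change 0.7 to 0.55, SE 0.17 to 0.21) and the matrix list went from −0.55 to −0.22 (adjusted p = 0.0196), so that share stays open in liver. Macrophage markers, the 1 cell type list called there, stayed called (−0.5 to −0.42, camera adjusted p = 0.000376). Their median lay only just beyond the SD over members (0.4), which does not measure the spread between animals, so that share stays open for them too. In muscle 620 of 1264 stayed called, under 50% as predicted for a cause, but a larger SE (0.12 to 0.15) can end calls too, and the median change was 0.51 before and 0.5 after, which argues against that share as the whole cause over these genes, though it stays open for single genes among the 644 whose calls ended (0.48 to 0.41, SE 0.13 to 0.16). The muscle matrix list (−0.65 to −0.85, adjusted p = 3.18e-15) and all 3 cell type lists called, macrophage (−0.64 to −0.87, 1.36e-08), endothelial (−0.5 to −0.52, 1.61e-06) and fibroblast (−0.36 to −0.39, 0.0079), kept their change, which argues against it for those lists. Growth stage may be a candidate, untested, and cannot be told apart from slaughter batch, since each time was 1 batch.

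Animal deviations from the group means were compared with the deviation of FBXO32 and TRIM63 in muscle, as a possible sign of feeding or fasting at slaughter, over 19 animals and 4 relations. The 9 liver feeding genes, among them ACLY and ACACA of fatty acid synthesis, had Pearson r = −0.76 (permutation p = 0.0015, adjusted 0.003), Spearman rho −0.76 (permutation p = 0.0013) and −0.76 without the 2 extreme animals, while the other muscle fasting genes, from the same libraries and so not independent, had r = 0.8 (permutation p = 6e-05, adjusted 0.00024), rho 0.78 (permutation p = 5e-04) and 0.79. The liver fasting genes had r = 0.39 (permutation p = 0.24, adjusted 0.32), rho 0.39 (permutation p = 0.16) and 0.4, and the liver unspliced share r = 0.097 (permutation p = 0.72, adjusted 0.72), rho 0.026 (permutation p = 0.93) and 0.26, and neither missed p excludes anything. Feeding state may therefore have differed between animals of a group, as a hypothesis that the liver fasting genes leave unsettled.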
